A study of Mus musculus with 9 samples.

How the data were processed

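Gene expression was measured in murine bone marrow cells on 9 Affymetrix mouse arrays, 3 for each of 3 retroviral constructs. The constructs were the empty murine stem cell virus vector with an internal ribosome entry site and GFP, the same vector carrying a NUP98-HHEX fusion, and the same vector carrying a NUP98-HOXA9 fusion. Per the labels' protocols the cells were grown in RPMI1640 with IL-3, IL-6, murine SCF and serum, RNA was purified on Qiagen columns, and biotinylated cRNA was prepared by the standard Affymetrix procedure. RNA was taken 72 h after transduction. The array titles name the last construct NUP98/HOX and the series design text names it NUP98/HOXA9. The labels do not say whether GFP-positive cells were sorted before RNA was taken, nor from which species the inserted cDNAs came.

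The values are log2 probe set signals as deposited by the authors, between 5.297 and 14.424 over the 9 arrays. That they are log2 values was read from their range. The method of summarisation, background correction and normalization is not given in the sources used here. Array medians lay between 7.176 and 7.304, and lower quartiles between 6.172 and 6.293. They were used without further scaling. The number of arrays limits the precision, and p-values measure the spread between these arrays, which may be technical as well as biological. The labels number the arrays of a group as separate experiments.

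Of 22690 probe sets, 64 were controls. The platform's annotation gave exactly 1 gene for 20380 probe sets, several genes for 691 and none for 1555. Of the 20380, 20351 were matched through their Entrez identifiers to the RefSeq gene table of assembly GRCm38, which was used for names only. No coordinates are given, because the annotation used names no genome build. Each gene was represented by its probe set of highest mean, with probe sets marked as shared between transcripts avoided where another existed. This left 12393 genes, of which 4956 had more than 1 probe set.

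Groups were compared in limma 3.58.1 under R 4.3.3, with 1 mean per group over all 9 arrays, empirical Bayes moderation and 6 residual degrees of freedom before moderation. P-values are two-sided and adjusted by the Benjamini-Hochberg procedure over all genes of a contrast, with a threshold of 0.05. Values are given as group mean ± SD (n = 3), differences as log2 difference ± SE of the fit. The 3 contrasts were NUP98-HHEX against vector, NUP98-HOXA9 against vector and NUP98-HHEX against NUP98-HOXA9.

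The labels number the arrays of every group as experiments 1 to 3, so arrays with the same number come from the same experiment and form pairs. Deviations from the group means correlated between 0.084 and 0.883 for the 9 pairs of arrays with the same number (median 0.717), the lowest being vector and NUP98-HOXA9 of experiment 2. They correlated between -0.755 and 0.315 for the 18 pairs with different numbers (median -0.288). The first principal component held 53.5% of the variance and set experiment 3 apart from experiments 1 and 2. The second held 16.4% and set NUP98-HOXA9 apart from the other constructs. The comparison fixed beforehand had no term for the experiment, so its counts, SEs and adjusted p-values do not use the pairing. A fit with the experiment number as a replicate block, which has 4 residual degrees of freedom, is given beside it for each gene and list described where it changed the call, and for the counts of a contrast or of a list described there that moved by over 1.5 times.

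Gene lists were written from general knowledge of mouse haematopoiesis. They comprised 22 lists with 598 genes, of which 519 were measured. Among them were lists for cell types that a marrow culture could hold. Lists were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists of a contrast. The same test with the correlation estimated per list and fry were run beside it. With the estimated correlation 1 list passed against vector with NUP98-HOXA9 and 1 between the fusions, in both contrasts the mast cell and basophil genes, and none passed with NUP98-HHEX against vector.

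The genes named were chosen by rule. For each contrast these were the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 values in one group all lay above the 3 of the other. Where fewer passed, genes of smallest p filled up to 4 per direction. From each list up to 4 members of smallest p were added where the list or at least 3 members passed, otherwise up to 2. Nup98, Hhex, Hoxa9, Hoxa5, Hoxa7, Hoxa10, Meis1, Pbx3, Flt3, Kit and Cd34 were taken in the contrasts against vector whatever their values, since the HOX genes and Flt3 were known to be of interest to the study. Prnp and Podxl against vector, and Angpt1, Itgb7 and Cpa3 with NUP98-HOXA9 against vector, lie outside this rule and were named after their values were seen. Genes of the shared response were the 6 of largest mean absolute difference called in both contrasts. Clone names were skipped. Groups, tests, lists, this rule and most of the other settings tried were fixed before the data were examined.

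The comparisons were tested on simulated arrays built from the measured means, experiment effects and residual variances, with 5 simulations per contrast, 12393 genes and 200 changed genes in each. For NUP98-HHEX against vector, 50.7% of genes changed by 0.5 log2, 91.6% of those changed by 1 and 97.3% of those changed by 2 were recovered without the block, and 95.2%, 100% and 100% with it. For NUP98-HOXA9 against vector the shares were 54.3%, 89.6% and 97.6% without the block, and for NUP98-HHEX against NUP98-HOXA9 49%, 92.8% and 98.2%. These shares hold for contrasts with 200 changed genes. Where fewer genes are called, as with NUP98-HHEX against vector, the adjustment is stricter and fewer changes would be recovered. There Mcpt1 (-1.44 log2, adjusted p 0.215) and Hs6st2 (-1.11, 0.116) did not pass without the block. False calls made up at most 0.4% of the simulated calls without the block and at most 7.4% with it. A simulated list of 19 independent genes lowered by 0.8 log2 had an unadjusted camera p under 0.05 in 5 of 5 simulations of each contrast. Lists of correlated genes were not simulated.

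Alternatives were the replicate block, leaving out each array, fitting only the 2 groups compared, quantile normalization, median centring, a filter on dim genes, averaging the probe sets of a gene, testing every probe set, an intensity trend with robust moderation, array weights and other thresholds. Leaving out whole experiments was added after the data had been seen. Probe sets with no gene or several genes were kept out of the gene comparisons. Figures were drawn with matplotlib 3.10.9.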

Results

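NUP98-HHEX and NUP98-HOXA9 are fusions of the nucleoporin NUP98 with a homeodomain transcription factor, and the series title links NUP98-HHEX to acute myeloid leukaemia. Bone marrow cells of the mouse were transduced with a retrovirus carrying one of the fusions or with the empty vector, and their RNA was hybridised 72 h later. Each construct was measured on 3 arrays, 1 from each of 3 experiments, and each array gave 12393 genes on a log2 scale. Array medians spanned 7.176 to 7.304. Arrays of the same experiment correlated at 0.9874 to 0.9977 over genes, arrays of the same construct at 0.9804 to 0.9942. The 3′ minus 5′ signal of the beta-actin controls, a sign of RNA quality, averaged 0.158 log2 on vector arrays, 0.231 on NUP98-HHEX arrays and 0.298 on NUP98-HOXA9 arrays. In experiment 2 it was 0.165 with NUP98-HOXA9 and 0.166 with vector. For the transferrin receptor controls this signal was 1.294, 1.186 and 1.221 with NUP98-HOXA9 in experiments 1 to 3, and 1.085, 0.920 and 1.140 with vector. For the Gapdh controls it was -0.097, -0.178 and -0.072 with NUP98-HOXA9, and -0.145, -0.178 and -0.170 with vector.

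The levels of the genes named in the constructs were read first. The single Nup98 probe set measured 8.15 ± 0.24 (SD, n = 3) with vector, 8.16 ± 0.32 with NUP98-HHEX and 8.23 ± 0.22 with NUP98-HOXA9. The single Hhex probe set measured 9.60 ± 0.13, 9.63 ± 0.05 and 9.69 ± 0.02. Neither differed by more than the spread between arrays, and the labels do not say whether these probe sets lie in the parts the vectors carry. Hoxa9 measured 9.17 ± 0.07, 10.04 ± 0.19 and 11.59 ± 0.09. Its second probe set moved in the same direction, from at most 7.89 on the vector arrays to between 8.04 and 8.13 with NUP98-HHEX and between 9.12 and 9.18 with NUP98-HOXA9. Whether the Hoxa9 signal on the NUP98-HOXA9 arrays includes RNA of the construct is left open by the labels.

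The first question was which genes NUP98-HHEX changed against the empty vector. With NUP98-HHEX, 1 gene passed the threshold, a signal assigned to Mycn, which encodes a MYC family transcription factor. Its probe set of highest mean measured 13.19 ± 0.14 (SD, n = 3) with vector and 11.88 ± 0.03 with NUP98-HHEX, a log2 difference of -1.31 ± 0.07 (SE) with an adjusted p of 0.000595. Its other 2 probe sets lay higher with NUP98-HHEX, by 0.49 ± 0.37 and 0.21 ± 0.10, and the mean of the gene's probe sets did not pass. With the experiment as a replicate block 10 genes passed, 6 higher and 4 lower, among them 3 genes of the HOX programme. An unadjusted p under 0.05 was reached by 157 genes (1.3%) without the block and by 448 (3.6%) with it. Both lay below a share of 0.05. Without the block, differences between experiments count as spread between arrays, so unchanged genes would give less than 0.05. The count without the block therefore cannot tell whether there was an excess, and the count with it shows none.

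**Figure D1:**
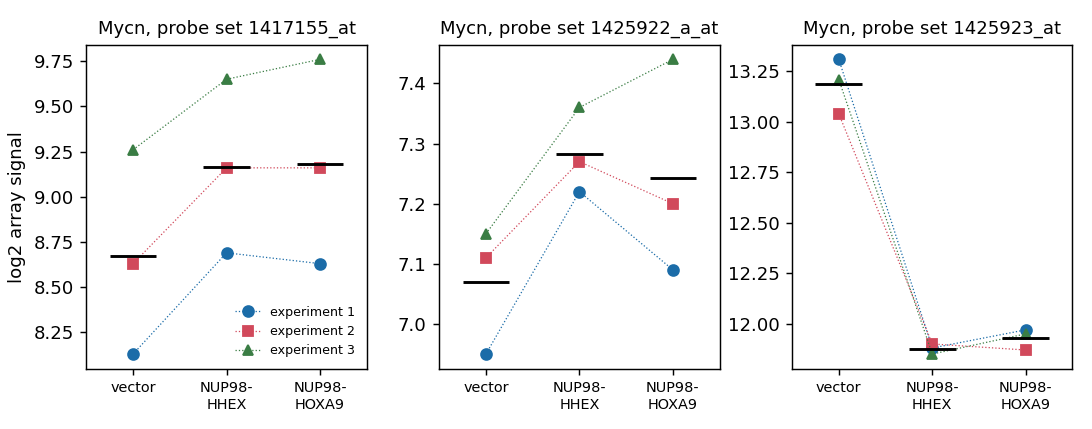
Log2 signal of the 3 probe sets of Mycn on each array (y axis, different range in each panel) for the 3 constructs (x axis), with 1 marker per experiment, dotted lines joining arrays of an experiment and black bars for group means. The probe set of highest signal had means of 13.19, 11.88 and 11.93 with vector, NUP98-HHEX and NUP98-HOXA9, while the other 2 probe sets lay higher with both fusions in each experiment.

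Hoxa9 itself lay 0.88 ± 0.10 log2 above vector with NUP98-HHEX (adjusted p 0.0862, and 0.0208 with the replicate block). Pbx3, which encodes a TALE homeodomain cofactor of HOX proteins, lay 0.66 ± 0.09 higher (0.116 and 0.0205), and Hoxa5 0.54 ± 0.10 higher (0.431 and 0.0242). These 3 genes passed only with the block, and all 3 lay higher in 3 of 3 experiments. Hoxa7 (+0.30 ± 0.11), Hoxa10 (+0.47 ± 0.14) and the HOX cofactor gene Meis1 (+0.16 ± 0.19) did not pass in either fit. Of the 26 measured HOX and TALE cofactor genes, none passed among all genes without the block, and 3 passed when adjusted over the list alone, all higher. The list shifted up (camera adjusted p 5.46e-07, and 0.156 with an estimated correlation), although its median was only 0.05 log2 and 9 of the 26 differences were negative.

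Genes of smallest p outside the HOX list were Tcf12, encoding an E protein, which lay 0.74 ± 0.10 log2 higher (adjusted p 0.116, with the block 0.0406), and Gphn, encoding gephyrin, 0.47 ± 0.07 higher (0.215 and 0.122). On the lower side were the heparan sulfate sulfotransferase gene Hs6st2 (-1.11 ± 0.14, adjusted p 0.116, with the block 0.0129, other probe sets -0.65 and -0.08), the small muscle protein gene Smpx (-0.81 ± 0.12, 0.215 and 0.0129) and Kit, the stem cell factor receptor gene (-0.63 ± 0.09, 0.209 and 0.0758). Smpx lay at 6.03 with NUP98-HHEX, below the lower quartile of every array, so its difference is a lower bound. With the block Prnp, the prion protein gene (+1.14, adjusted p 0.0129), and Podxl, encoding podocalyxin (+0.56, 0.0242), also passed, and both are named because they complete the 10 and were chosen after their values were seen. Flt3, a receptor gene of early progenitors, differed from vector by 0.25 ± 0.14 and Cd34, a progenitor surface marker, by -0.45 ± 0.15. Neither passed in either fit.

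Among mast cell and basophil genes, the mast cell protease gene Mcpt1 lay 1.44 log2 below vector with NUP98-HHEX (-1.44 ± 0.22, adjusted p 0.215, with the block 0.0142). Mcpt4 (-1.12 ± 0.20), the tryptase gene Tpsab1 (-0.78 ± 0.15) and the IgE receptor gene Fcer1a (-0.36 ± 0.09) lay lower in 3 of 3 experiments and did not pass in either fit. Of 19 measured members 4 passed when adjusted over the list alone, all lower, and the list shifted down (camera adjusted p 6.28e-06, and 0.156 with an estimated correlation). The list's median difference was -0.16, 0.04 and -0.27 in experiments 1 to 3.

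Erythroid genes shifted up (camera adjusted p 8.37e-05), with none of 28 past the threshold. The erythroid transcription factor gene Klf1 differed by 0.43 ± 0.13 and the carbonic anhydrase gene Car1 by 0.42 ± 0.18. Late neutrophil genes shifted down (0.0033), with none of 25 past the threshold. Errors without the block were wide for members such as Ifitm6 (-0.74 ± 0.69) and the formyl peptide receptor gene Fpr2 (-0.82 ± 0.81). With the block their SEs were 0.19 and 0.22. Both lay lower in 3 of 3 experiments, but neither passed with the block (adjusted p 0.494 and 0.562). The late neutrophil list turned direction without NUP98-HHEX of experiment 2 (0.198). Primary granule genes (0.0358) and eosinophil genes (0.0184) shifted down, and p53 targets (0.0103) and amino acid response genes (0.0184) shifted up. Primary granule genes turned direction without vector of experiment 1 (0.863), and amino acid response genes without vector of experiment 2 (0.678) or NUP98-HHEX of experiment 3 (0.579). None of these lists passed with an estimated correlation, the adjusted p being 0.473 for erythroid, 0.922 for late neutrophil, 0.922 for primary granule, 0.473 for eosinophil, 0.483 for p53 and 0.922 for amino acid response genes. The replicate block added interferon response genes, lower (camera adjusted p 0.49 without and 9.3e-08 with the block), mitosis genes, lower (0.0849 and 0.00304), monocyte genes, lower (0.227 and 0.0146), megakaryocyte genes, lower (0.515 and 0.0219), and immediate early genes, higher (0.0597 and 0.0145). Of these the interferon, mitosis and megakaryocyte lists turned direction in the fit without the block when 1 array was left out. None of the members of these 5 lists passed, and none of the 22 lists passed with the block and an estimated correlation.

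The next question was which genes NUP98-HOXA9 changed. With NUP98-HOXA9, 148 genes passed the threshold against vector, 102 higher and 46 lower, and 40 of them changed at least 2-fold (22 higher, 18 lower). With the replicate block 712 genes passed, 433 higher and 279 lower, including all 148. Among them Hoxa5, Hoxa9, Hoxa7 and Pbx3 rose, as did the progenitor genes Flt3 and Eya1, and 8 of 19 mast cell and basophil genes fell. Without 1 array the count lay between 60 and 119, so leaving out vector of experiment 1, 2 or 3 (60, 86 and 71 genes), NUP98-HOXA9 of experiment 1, 2 or 3 (95, 93 and 81) or NUP98-HHEX of experiment 2 (93) each moved it by over 1.5 times.

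Hoxa5 showed the smallest p, with 6.88 ± 0.11 (SD, n = 3) for vector and 9.38 ± 0.17 for NUP98-HOXA9, a rise of 2.49 ± 0.10 log2 (SE, adjusted p 2.07e-05). Hoxa9 rose by 2.42 ± 0.10 (2.07e-05), Pbx3 by 1.69 ± 0.09 (9.12e-05) and Hoxa7 by 0.94 ± 0.11 (0.00626). The Hoxa9 signal, which also enters the list below, may include RNA of the construct. Hoxa10 (+0.40 ± 0.14) and Meis1 (+0.29 ± 0.19) did not pass in either fit. Of the 26 HOX and TALE cofactor genes 5 passed, all higher, and 7 passed when adjusted over the list alone, all higher. The list shifted up (camera adjusted p 2.31e-08, and 0.115 with an estimated correlation), although its median was only 0.10 log2.

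**Figure D2:**
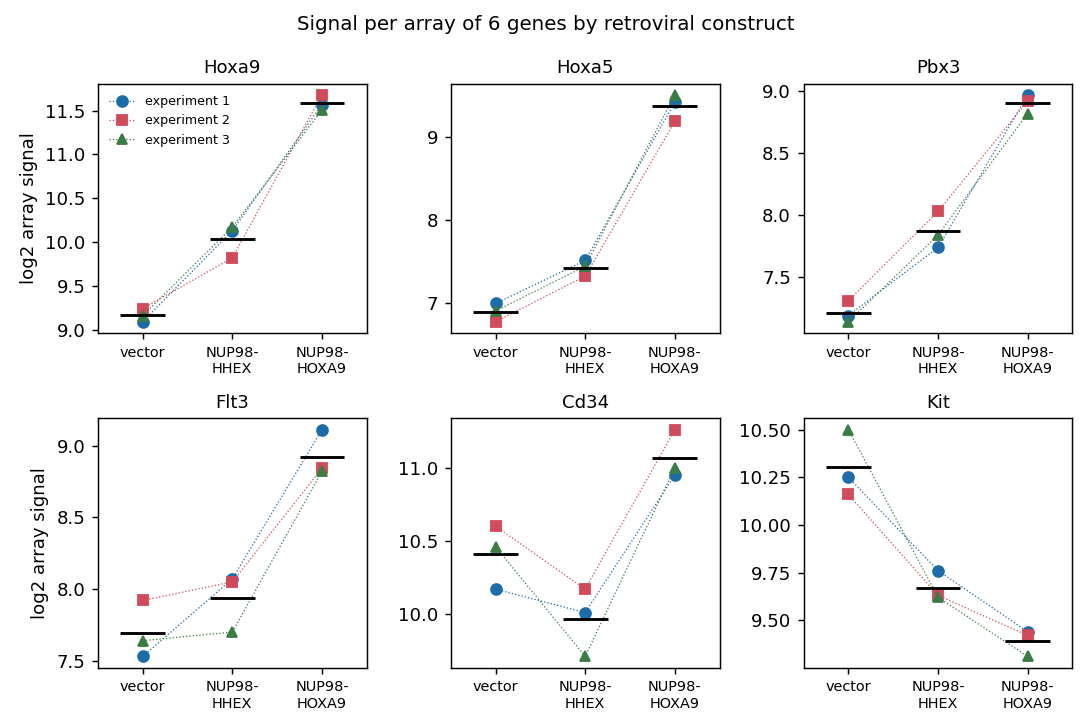
Log2 signal of Hoxa9, Hoxa5, Pbx3, Flt3, Cd34 and Kit on each array (y axis, different range in each panel) for the 3 constructs (x axis), with 1 marker per experiment and black bars for group means. Hoxa9 means were 9.17, 10.04 and 11.59, and Kit means were 10.30, 9.67 and 9.39 with vector, NUP98-HHEX and NUP98-HOXA9.

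Stem and progenitor genes moved both ways, with 2 of 31 higher and 3 lower (8 and 7 with the replicate block). Flt3 rose by 1.23 ± 0.14 log2 (adjusted p 0.00482) and Eya1, encoding a transcriptional coactivator, by 0.65 ± 0.07 (0.00426). Kit fell by 0.91 ± 0.09 log2 (0.00328), and the Mycn signal fell by 1.25 ± 0.07 (0.000117), again with the gene's other probe sets higher. The Mycn call was lost in 1 of 17 settings, with the mean of all probe sets of a gene. Angpt1, encoding an angiopoietin, also fell (-0.56 ± 0.10, 0.0385), a call lost in 9 of 17 settings, 8 of them single arrays left out. Cd34 lay 0.66 ± 0.15 higher, with an adjusted p of 0.107 and of 0.00585 with the replicate block. The list as a whole did not shift (camera adjusted p 0.918).

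The mast cell and basophil genes fell most broadly. Of 19 measured members 8 fell and 1 rose, the integrin gene Itgb7 (+0.65 ± 0.11, adjusted p 0.0287, lost in 9 of 17 settings), and 14 fell when adjusted over the list alone. The mast cell protease genes Mcpt2 (-3.28 ± 0.43 log2, adjusted p 0.00908), Mcpt1 (-2.34 ± 0.22, 0.00238) and Mcpt4 (-2.30 ± 0.20, 0.00114) fell, as did Tpsab1 (-2.73 ± 0.15, 0.00011). Mcpt1 lay at 6.13 with NUP98-HOXA9, below the lower quartile of every array, so its fall is a lower bound. Tph1, which encodes a tryptophan hydroxylase of serotonin synthesis (-1.71 ± 0.12, 0.000318), the tryptase gene Tpsb2 (-1.67 ± 0.20, 0.00729, its other probe set -0.23) and Fcer1a (-1.17 ± 0.09, 0.000611) fell. The mast cell carboxypeptidase gene Cpa3, at 12.92 with vector, differed by -0.40 ± 0.12 and passed only with the block (adjusted p 0.231 and 0.0162). The list's median was -0.83 (camera adjusted p 1.27e-21, and 0.0097 with an estimated correlation), and -0.99, -0.47 and -1.27 in experiments 1 to 3. On the same arrays the 3′ minus 5′ beta-actin signal was 0.337, 0.165 and 0.392. With the block 15 members fell.

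**Figure D3:**
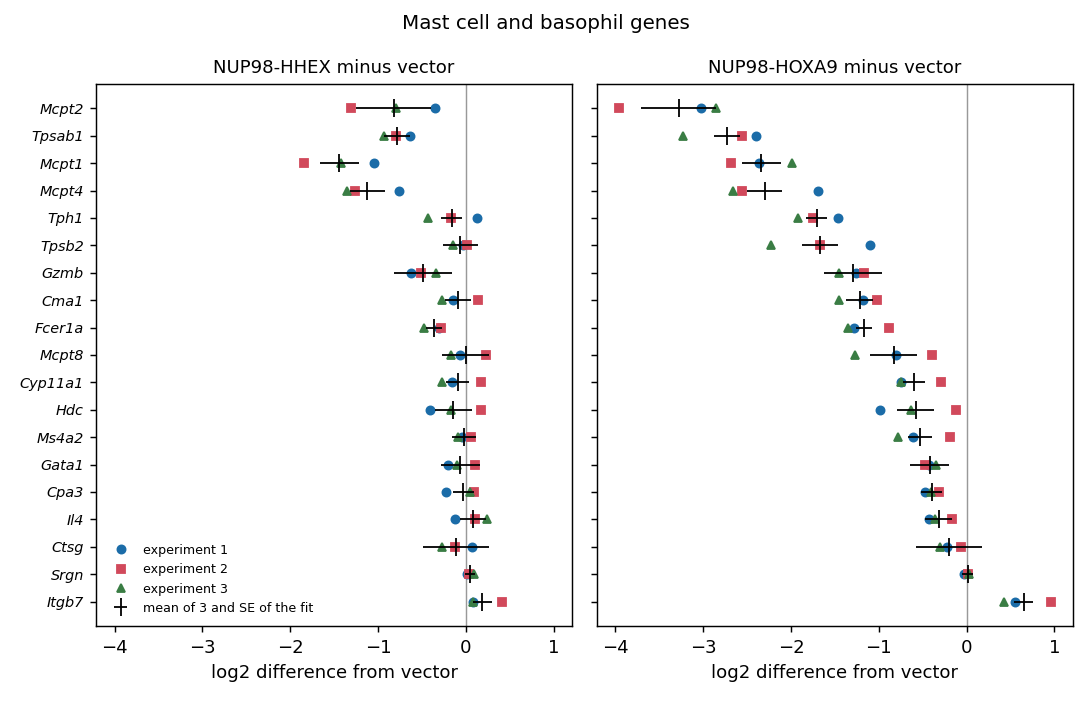
Log2 difference from the vector array of the same experiment (x axis) for 19 mast cell and basophil genes (y axis), with 1 marker per experiment. A black tick gives the mean of 3 experiments, and its bar the SE of the fit without the replicate block. With NUP98-HOXA9 the mean differences ran from -3.28 for Mcpt2 to 0.65 for Itgb7, and with NUP98-HHEX from -1.44 for Mcpt1 to 0.19 for Itgb7.

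Outside these lists the largest rises were those of Crisp3, encoding a cysteine-rich secretory protein (+3.24 ± 0.26 log2, adjusted p 0.000753), the germ cell helicase gene Ddx4 (+2.85 ± 0.15, 9.12e-05), the milk casein gene Csn2 (+2.63 ± 0.17, 0.000199) and Erv3, named for an endogenous retrovirus (+2.40 ± 0.14, 0.000117). The vector levels of these 4 genes lay between 5.68 and 5.92, close to the lowest value of the arrays, so their rises are lower bounds. The lectin gene Clec10a (+1.76 ± 0.10, 0.00011) and Calcrl, encoding a peptide receptor (+1.73 ± 0.20, 0.00582), also rose. Among falls were the carbonic anhydrase-related gene Car8 (-2.31 ± 0.23, 0.00255, its other probe set only -0.15) and Ddc, encoding an aromatic amino acid decarboxylase (-1.87 ± 0.24, 0.00819).

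Several smaller groups also moved. Of 24 stromal and endothelial genes 4 rose, namely Igfbp7 (+1.32 ± 0.17, adjusted p 0.00857), Pdgfrb (+0.99 ± 0.16, 0.0224), Postn (+0.49 ± 0.06, 0.00857) and Cxcl12 (+0.40 ± 0.06, 0.0143, its other probe set +0.11), and the list shifted up (camera adjusted p 0.00586). The other 2 probe sets of Igfbp7 differed by only -0.01 and 0.19. Postn and Cxcl12 lay at 6.05 and 6.01 with vector, below the lower quartile of every array, so their rises are lower bounds. Of 28 erythroid genes Car1 (+1.54 ± 0.18, 0.00534) and Rhag, encoding a red cell membrane glycoprotein (+1.26 ± 0.14, 0.00482), rose, without a shift of the list (0.0772), and with the block 4 members rose and 1 fell. Rhag lay at 6.15 with vector, again below every lower quartile, so its rise is a lower bound too. Of 14 primary granule genes Nkg7 fell (-1.44 ± 0.18, 0.00782), with the block 6 fell, and the list shifted down (0.00135). Myeloperoxidase (Mpo) differed by -0.61 ± 0.37 and passed only with the block (adjusted p 0.762 and 0.00422). Of 9 eosinophil genes the chemokine gene Ccl6 (-1.34 ± 0.17, 0.00819) and Siglecf (-0.57 ± 0.10, 0.0328) fell and Ccl9 rose (+0.44 ± 0.07, 0.0273), with a shift of the list that was lost with the block (0.049 and 0.0516). The stress-responsive gene Sesn1 was the 1 of 21 p53 targets that rose (+1.03 ± 0.17, 0.0277), 3 rose with the block, and the list shifted up (0.00163). Mitosis and replication genes shifted down (0.000221), and immediate early (0.00704), amino acid response (0.0248) and MHC class II genes (0.000811) shifted up, with no member past the threshold without the block. The amino acid response list turned direction without experiment 2 (0.787). Some of these calls were lost when arrays were left out or only the 2 groups were compared, namely Siglecf in 9 of 17 settings (quantile normalization among them), Ccl9 in 8, Sesn1 in 7, Pdgfrb in 4 and Cxcl12 in 6 of 16. With an estimated correlation the adjusted p was 0.752 for stromal, primary granule, eosinophil, immediate early and MHC class II genes, 0.539 for p53 targets, 0.833 for mitosis and 0.853 for amino acid response genes.

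The replicate block added members to several lists. Of 20 MHC class II and dendritic cell genes 10 rose with it, such as H2-DMa (+0.55, adjusted p 0.138 without and 0.00605 with the block) and the chemokine gene Ccl22 (+0.94, 0.559 and 0.00245), and the list then passed with an estimated correlation (adjusted p 0.0323). Of 26 inflammatory cytokine and NF-kB genes 11 rose and 2 fell with it, one of these Il6 (-1.79 ± 0.41, adjusted p 0.107 without and 9.23e-05 with the block). Of 28 interferon response genes 4 rose with it, among them Gbp2 (+0.93 ± 0.93, 0.938 and 0.000518). As lists, inflammatory genes (camera adjusted p 0.117 without and 2.32e-08 with the block) and interferon response genes (0.28 and 1.02e-08) shifted up only with it, and late neutrophil (0.074 and 1.12e-06) and megakaryocyte genes (0.117 and 0.000398) shifted down only with it. With the block and an estimated correlation the adjusted p was 0.21 for the first pair and 0.324 for the second. The transcriptional regulator gene Nupr1 rose by 2.49 ± 0.63 (0.151 and 8.79e-05), and 6 of 29 amino acid response genes did so with the block. Of 25 late neutrophil genes 6 fell and 1 rose, and 4 of 18 megakaryocyte genes fell and 1 rose. Of 38 mitosis and replication genes 5 fell, Rrm2 among them (-0.63 ± 0.22, 0.359 and 0.00167). Of 25 immediate early genes 5 rose, of 26 hypoxia genes 3 rose and 1 fell, of 31 monocyte genes 1 rose and 1 fell, and of 19 cholesterol synthesis genes 1 rose, all only with the block.

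The 2 fusions were compared directly in the last contrast. Against NUP98-HOXA9, 67 genes passed with NUP98-HHEX, 19 higher and 48 lower, and 25 of them differed at least 2-fold. With the replicate block 423 passed, 102 higher and 321 lower, including all 67. Among them 6 of 19 mast cell and basophil genes were higher with NUP98-HHEX, and Hoxa5, Hoxa9 and Pbx3 were lower. Flt3 and Cd34 were lower too, but lost the call in 8 and 7 of 17 settings. Without 1 array the count lay between 19 and 60, and 7 single arrays moved it by over 1.5 times, to 40 without vector of experiment 1, to 26, 19 and 32 without NUP98-HHEX of experiments 1 to 3 and to 37, 30 and 38 without NUP98-HOXA9 of experiments 1 to 3.

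With NUP98-HHEX, Hoxa5 was 1.95 ± 0.10 log2 lower than with NUP98-HOXA9 (-1.95, adjusted p 0.000188), Hoxa9 (-1.54 ± 0.10, 0.000449) and Pbx3 (-1.03 ± 0.09, 0.00119) were lower, and Hoxa7 passed only with the block (-0.63 ± 0.11, 0.0565 and 0.0121). The Hoxa9 difference, which also enters the list, may include RNA of the construct on the NUP98-HOXA9 arrays. Of the 26 HOX and TALE cofactor genes 3 were lower (5 when adjusted over the list alone), and the list shifted down (camera adjusted p 1.19e-05, and 0.268 with an estimated correlation). Cd34 was at 9.96 ± 0.23 (SD, n = 3) with NUP98-HHEX and 11.07 ± 0.17 with NUP98-HOXA9 (-1.11 ± 0.15, adjusted p 0.02), and Flt3 differed by -0.98 ± 0.14 (0.0254). Both calls were lost without any single array of either fusion and with only the 2 groups compared, and that of Flt3 with quantile normalization. Angpt1 was higher with NUP98-HHEX (+0.66 ± 0.10, 0.0335, lost in 9 of 17 settings). Ddx4 (-2.84 ± 0.15, 0.000188), Crisp3 (-3.16 ± 0.26, 0.00107), Csn2 (-2.55 ± 0.17, 0.000467), Erv3 (-2.04 ± 0.14, 0.000589), Clec10a (-1.75 ± 0.10, 0.000232) and the casein gene Csn1s2b (-1.50 ± 0.15, 0.00413) were lower. With NUP98-HHEX, Ddx4, Crisp3, Csn2 and Csn1s2b lay below 6.172, the lowest of the arrays' lower quartiles, so these 4 differences are lower bounds. The erythroid genes Car1 (-1.11 ± 0.18, 0.04, lost in 9 of 17 settings, quantile normalization among them) and Rhag (-0.99 ± 0.14, 0.0254, lost in 6 of 16) were lower too.

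Of the 19 mast cell and basophil genes 6 were higher with NUP98-HHEX than with NUP98-HOXA9, and 14 when adjusted over the list alone. With the replicate block 14 were higher and 1 lower. Tpsab1 differed by 1.95 ± 0.15 log2 (adjusted p 0.000772), Tpsb2 by 1.61 ± 0.20 (0.0154, its other probe set 0.21), Tph1 by 1.56 ± 0.12 (0.000772), Mcpt4 by 1.18 ± 0.20 (0.0484) and Fcer1a by 0.81 ± 0.09 (0.00878). The list's median was 0.80 (camera adjusted p 4.6e-22, and 0.00918 with an estimated correlation), and 0.64, 0.61 and 0.69 in experiments 1 to 3, while the 3′ minus 5′ beta-actin signal was lower with NUP98-HHEX in experiments 1 and 3 and higher in experiment 2. Outside the list the aldo-keto reductase gene Akr1c18 (+2.01 ± 0.27, 0.0194), Car8 (+1.69 ± 0.23, 0.0194, its other probe set +0.08), Ccl6 (+1.28 ± 0.17, 0.0194) and Nkg7 (+1.24 ± 0.18, 0.0258) were higher with NUP98-HHEX. Of the calls in this paragraph, those lost in some of 17 settings were Mcpt4 in 10, Nkg7 in 8 (both with quantile normalization among them), Car8 and Ccl6 in 6, and Tpsb2 and Akr1c18 in 4, otherwise mostly without single arrays. MHC class II genes (0.000804) and stromal genes (0.00109) shifted down, mitosis (0.00323) and primary granule genes (0.0299) up, each with an adjusted p of 0.971 with an estimated correlation. With the block 12 of the 20 MHC class II genes were lower with NUP98-HHEX, and the list passed with an estimated correlation (0.0299). Interferon response genes shifted down only with the block (camera adjusted p 0.103 and 6.85e-19, and 0.149 with the block and an estimated correlation), with 6 of 28 members lower, Gbp2 among them (-1.11 ± 0.93, 0.999 and 0.000346). Inflammatory genes did likewise (0.178 and 3.28e-09, and 0.233 with the block and an estimated correlation), although Il6 was higher (+1.52 ± 0.41, 0.263 and 0.00035). Nupr1 was lower only with the block (-2.11 ± 0.63, 0.353 and 0.00035). Further lists that passed camera only with the block were immediate early (0.000102), p53 target (0.00545), monocyte (0.00855), hypoxia (0.0151), amino acid response (0.0212) and B lineage genes (0.0264), all lower with NUP98-HHEX, and megakaryocyte genes (0.00579), higher. Their adjusted p with the block and an estimated correlation lay between 0.364 and 0.542. Members higher and lower with the block numbered 2 and 5 of 31 stem and progenitor genes (1 and 2 without it), 0 and 4 of 24 stromal genes (0 and 2), 2 and 0 of 14 primary granule genes (1 and 0), 1 and 4 of 26 inflammatory genes, 0 and 5 of 25 immediate early genes and 0 and 3 of 21 p53 targets. They also numbered 1 and 2 of 31 monocyte genes, 2 and 2 of 18 megakaryocyte genes, 0 and 2 of 26 hypoxia genes, 0 and 2 of 29 amino acid response genes, 1 and 1 of 19 B lineage genes and 1 and 0 of 38 mitosis genes, none of them without the block.

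The response shared by the 2 fusions was then measured. The signal assigned to Mycn was the 1 gene called in both contrasts against vector, in the same direction. With the replicate block 9 of the 10 genes called with NUP98-HHEX were also called with NUP98-HOXA9 in the same direction, 5 higher and 4 lower, and none was called in opposite directions. Independent lists would share 0.21 and 0.0901, values that leave out the shared vector arrays. Groups simulated as unchanged, with shared vector arrays, shared 0.01 calls on average (at most 1) in 100 simulations. With both fusion groups unchanged hardly any gene can be called in either contrast, so that value says nothing about the 9 shared calls. The higher ones were Hoxa9, Hoxa5, Pbx3, Tcf12 and Prnp, the lower ones Mycn, Hs6st2, Smpx and Mcpt1, and Podxl was called with NUP98-HHEX alone (-0.09 with NUP98-HOXA9, adjusted p 0.645 with the block). On the NUP98-HOXA9 arrays the Hoxa9 signal may include RNA of the construct. Tcf12 differed from vector by 0.74 and 0.60 log2 with NUP98-HHEX and NUP98-HOXA9, Prnp by 1.14 and 1.17 (with NUP98-HOXA9 adjusted p 0.0532, and 0.000557 with the block), Smpx by -0.81 and -0.86 and Hs6st2 by -1.11 and -1.56. Smpx lay at 6.03 and 5.98 with the fusions, below the lower quartile of every array, so its falls are lower bounds and their likeness says little. With NUP98-HOXA9 the calls without the block were lost for Tcf12 in 6 of 17 settings and for Smpx in 5 of 16.

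Of the 148 genes called with NUP98-HOXA9, 129 (87.2%) had the same sign with NUP98-HHEX, against 66.0% (at most 71.3%) in 100 simulations with shared vector arrays, an unchanged NUP98-HHEX group and the NUP98-HOXA9 differences kept for all genes. These simulations called 557 genes on average, so their share is that of a longer and weaker set. With the differences kept only for the called genes 132 were called on average, and the share was 53.7%. Genes were called anew in each simulation and were simulated as independent. Over all genes the share was 65.4%, and 58.6%, 51.7% and 53.7% between experiments without a shared array. Groups simulated as unchanged, NUP98-HOXA9 included, gave 66.7%, which cannot tell whether a response was shared. By direction the 129 genes were 88 of 102 risen and 41 of 46 fallen genes. The median ratio of the NUP98-HHEX to the NUP98-HOXA9 difference was 0.21 on the log2 scale (quartiles 0.07 and 0.37), and 60 of the 148 genes differed between the fusions (115 with the block). Over all genes the 2 sets of differences correlated at 0.495, at 0.107 without NUP98-HHEX of experiment 3 and at 0.744 without vector of experiment 3. Leaving out 1 array makes the groups unequal in experiments. Without experiment 1, 2 or 3 as a whole the correlation was 0.45, 0.54 and 0.421. Simulated unchanged groups that share vector arrays gave 0.503 (at most 0.557). That simulation left NUP98-HOXA9 unchanged too, although its differences were wider than those with NUP98-HHEX (SD 0.209 and 0.096). It therefore cannot tell whether a response was shared over all genes. The covariance of the 2 sets was 0.00992, against 0.012 simulated without the block and 0.00374 with it, a difference of -0.00211 and of 0.00617. Without the block the simulation counted differences between experiments as spread of single arrays, which raised the simulated covariance. Differences taken from different experiments, which share no array, correlated at 0.306, 0.218 and 0.275. These last values rest on 1 vector array on one side and 2 on the other. Genes are not independent replicates, the 3 vector arrays cannot be split into 2 sets of at least 2, and part of any excess may come from them.

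**Figure D4:**
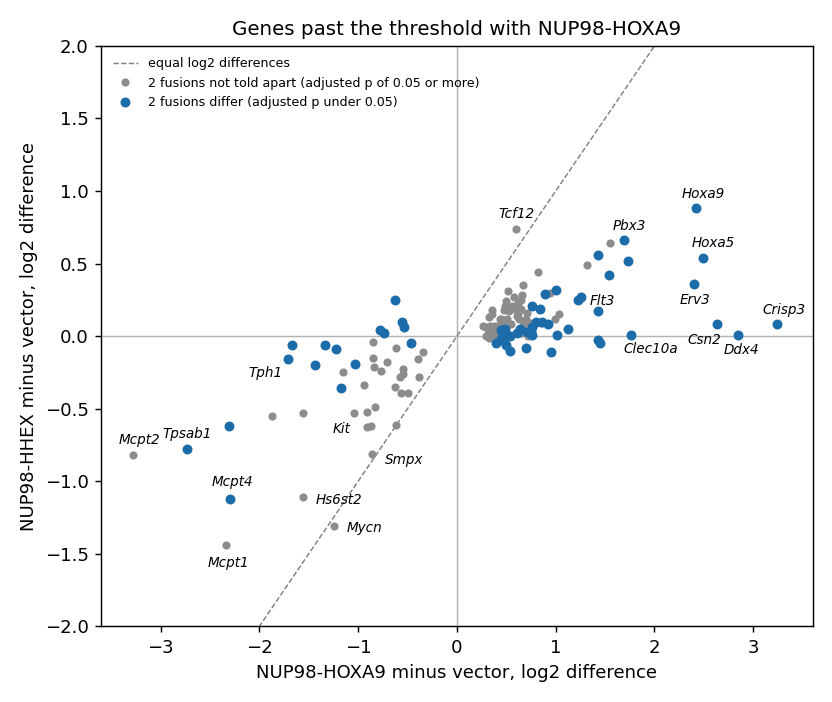
Log2 difference from vector with NUP98-HOXA9 (x axis) and with NUP98-HHEX (y axis, narrower range) of the 148 genes called with NUP98-HOXA9, each point the mean over 3 experiments. The 60 genes that also differed between the fusions are blue, and the dashed line marks equal differences. Mycn lies near the dashed line. Ddx4 and Crisp3 lie near 0 with NUP98-HHEX, and Smpx lies near the line with both fusions close to the lowest values of the arrays.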

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

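The tests of the Mycn probe sets and of fewer mast cells were chosen only after the result was seen, while those of chance splits, normalization and RNA quality were chosen before. A signal appeared in probe sets that the gene comparisons did not use. Of 2246 probe sets outside the gene table, which name no gene or several, 13 passed with NUP98-HOXA9 against vector in limma, 10 higher and 3 lower. The largest rise was that of probe set 1416325_at (4.84 log2, adjusted p 9.25e-07), and the largest fall that of 1425145_at (-0.83, 0.0178). Between the fusions 2 passed, both lower with NUP98-HHEX, with 1416325_at again the largest (-5.32, 4.12e-07). With NUP98-HHEX against vector the count was 0. An unadjusted p under 0.05 was reached by 27 probe sets, less than a share of 0.05 of the 2246, which cannot tell whether some of them changed. No gene is named for these probe sets.

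Splitting the 6 arrays of each contrast into 3 and 3 in all 10 ways cannot give a share under 0.05. The real grouping gave 1 gene with NUP98-HHEX against vector, 148 with NUP98-HOXA9 against vector and 67 between the fusions, and the highest count of any other split was 0 in each contrast, so 1 of 10 splits reached the real count each time.

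The Mycn signal lower with both fusions was set against a fall of Mycn mRNA as a whole. That reading predicted falls in the gene's other probe sets, but their differences from vector within an experiment lay above 0 in 12 of 12 cases, between 0.08 and 0.56 log2, which argues against it. The probe set could instead read RNA of the retroviral vector, which would give the fusions similar values. They differed by -0.05 log2 (adjusted p 0.999), a value that a shared biological effect on 1 transcript form would give as well. Probe and vector sequences were not used here, so this stays open.

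The lower mast cell and basophil genes with NUP98-HOXA9 were set against 3 other readings. After quantile normalization the median of the 19 members was -0.89 log2 (camera adjusted p 6.14e-21), which argues against remaining differences of scale between arrays. The arrays were already alike before it (medians 7.176 to 7.304), so an effect of the original normalization, which the sources do not give, was not tested. Fewer mast cells and basophils with unchanged expression would lower all members alike only if no other cell expressed them. Some members also stand in the lists of primary granule or erythroid genes, and Itgb7 rose. The members' differences had an SD of 1.02 against a median SE of 0.10 with the block. They kept their order over 3 experiments (Kendall W 0.953, permutation p 1e-05, the smallest that 100000 permutations can give). Expression in other cells and compressed bright or dim signals, not tested, would also spread them. The unequal falls therefore cannot decide whether such cells were fewer. With the beta-actin 3′ minus 5′ difference as a covariate beside the block, 13 of 15 members stayed lower, but this fit had 3 residual degrees of freedom and called 1452 genes against 712, so the calls say little by themselves. The median of all 19 members moved from -0.83 to -0.55 log2 (median SE 0.10 and 0.12), with 17 lower in both fits. This leaves part of the fall open to RNA quality but argues against RNA quality, as read from beta-actin, as the whole cause. The transferrin receptor and Gapdh controls, which also differed between these groups, were not used as covariates. An effect of NUP98-HOXA9 on mast cell genes remains a hypothesis.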

How the results depend on the processing

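Leaving out experiments, and leaving out arrays with the block, were added after the data had been seen. Where a value moved the cause was not tested, except that a stricter threshold lowers a count by construction. Leaving out 1 array without the block leaves its group short of 1 experiment. Differences between experiments then enter that group's contrasts, and the lists that turned direction without 1 array are open to this. With NUP98-HHEX against vector, the count of 1 became 10 with the replicate block, 4 with quantile normalization (50% higher, against 0% of 1), 3 with an intensity trend and robust moderation and 4 with array weights. It was 0 with the mean of all probe sets of a gene, which removed the Mycn call, and lay between 0 and 2 with arrays or experiments left out. It was 2 without vector, NUP98-HHEX or NUP98-HOXA9 of experiment 2 and 0 without any one experiment. Unadjusted p under 0.05 was reached by 157 genes (1.3%) in limma with all arrays and no block. Differences between experiments count as spread in that fit, so this share cannot tell whether there was an excess.

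With NUP98-HOXA9 against vector, the count of 148 became 712 with the block, 66 with only the 2 groups compared, 58 at an adjusted p under 0.01 and 40 with at least a 2-fold change. It lay between 13 and 119 with arrays or experiments left out (14, 13 and 95 without experiments 1, 2 and 3). Between the fusions the count of 67 became 423 with the block, 26 with only the 2 groups compared, 21 at an adjusted p under 0.01 and 25 with at least a 2-fold change, and lay between 4 and 60 with arrays or experiments left out (12, 4 and 56 without experiments 1, 2 and 3). With the block and 1 array left out the 3 counts lay between 1 and 31, 316 and 1251, and 136 and 645. With the block and experiment 1, 2 or 3 left out they were 2, 3 and 9, 150, 579 and 502, and 72, 218 and 381. Other settings kept both counts within 1.5 times.

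The count shared by both fusions, 1, became 9 with the block, 4 with quantile normalization, 0 with the mean of all probe sets, 3 with trend and robust moderation and 4 with array weights, and lay between 0 and 2 with arrays or experiments left out. The correlation of the 2 responses across genes, 0.495, lay between 0.107 without NUP98-HHEX of experiment 3 and 0.744 without vector of experiment 3. Both extremes came from fits with groups unequal in experiments. Without experiment 1, 2 or 3 as a whole, which keeps the groups equal, the correlation was 0.45, 0.54 and 0.421.

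No named gene changed direction past the threshold. Without experiments 1, 2 and 3, 40, 49 and 17 of the 64 called pairs of gene and contrast lost the call, so most named calls were lost without experiment 1 or 2. Over the other settings, whole experiments not counted, 939 of 1081 values kept the call and 142 lost it, and for 49 pairs not called 44 of 829 values passed. Named calls that were lost in some setting are given with the genes. Over the same settings, of 336 values for 24 called lists 245 kept the call, 87 lost it and 4 turned direction. Of 588 values for 42 lists not called 510 stayed so, 72 passed and 6 turned. The block ended the call of no gene and of 1 list, eosinophil genes with NUP98-HOXA9, and besides the added calls given with the genes and lists described it added calls of genes not named here. Lists that turned in some setting are given with the lowest and highest camera adjusted p over arrays or experiments left out. With NUP98-HHEX against vector these were primary granule and early granulocyte genes (3.33e-05 to 0.943), late neutrophil genes (2.18e-09 to 0.863), MHC class II and dendritic cell genes (0.00298 to 0.962), megakaryocyte genes (0.000268 to 0.665), interferon response genes (2.18e-06 to 0.826), mitosis and DNA replication genes (1.68e-06 to 0.863), inflammatory cytokine and NF-kB genes (3.38e-05 to 0.976) and amino acid response (ATF4) genes (1.7e-07 to 0.678). With NUP98-HOXA9 against vector these were amino acid response (ATF4) genes (1.16e-07 to 0.956), and between the fusions cholesterol synthesis genes (0.0128 to 0.884). Other pseudocounts were not run because the values are log2, and 3 arrays per group limit precision.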

Other observations

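Of 20 T and NK lineage genes 1 rose with NUP98-HOXA9, Cd7, a surface marker of early lymphoid and some myeloid cells (+0.56 ± 0.07 log2, adjusted p 0.0056), and 2 members fell with the replicate block, Lat, encoding a signalling adaptor of T cells and mast cells, among them (-0.97 ± 0.22, 0.107 without and 0.00106 with the block). Between the fusions 1 was higher and 1 lower with NUP98-HHEX, only with the block. Of 19 B lineage genes none passed without the block in any contrast, and with it the immunoglobulin heavy chain gene Ighm rose with NUP98-HOXA9 (+1.20 ± 0.44, 0.392 and 0.000935), while its other 10 probe sets differed by -0.06 to 1.26. Between the fusions Dntt, encoding a DNA polymerase of lymphoid progenitors, was higher with NUP98-HHEX only with the block (+0.42 ± 0.08, 0.0588 and 0.0211), and Ighm was lower (-0.75 ± 0.44, 0.945 and 0.0152). Ribosome biogenesis and MYC-responsive genes had medians of 0.01 with NUP98-HHEX and -0.02 with NUP98-HOXA9, with none of 29 past the threshold in either fit. Among p53 targets the BH3-only gene Pmaip1 passed with NUP98-HOXA9 only with the replicate block (+0.91 ± 0.40, adjusted p 0.556 and 0.000752).

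The test of a single share was chosen only after the result was seen. The smaller response to NUP98-HHEX was set against the same response occurring in a smaller share of the cells. Under that reading 1 share, estimated at 0.184, would predict every gene's difference from that with NUP98-HOXA9, but 17 of the 148 genes (11.5%) deviated. Several of these lay near the floor of the arrays with vector, so the test was repeated with the 109 genes whose 3 group means all lay above the 40th percentile of probe sets. Of these 9 (8.3%) deviated, 6 by more and 3 by less than predicted (14 genes, 12.8%, with the block). One of the 6 was Mycn, whose signal is in doubt, and without it 8 of 108 (7.4%) deviated, 5 by more and 3 by less. This argues against a single share only if signals are proportional to RNA amounts. Compressed bright or dim signals, not tested, could also make genes deviate. Clec10a differed by 0.01 log2 where 0.53 was predicted, while Tcf12 differed by 0.74 where 0.13 was predicted and Kit by -0.63 where -0.13 was predicted.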
